A study of Mus musculus with 8 samples.

How the data were processed

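RNA was sequenced from Tregs that the submitters had sorted from lymph nodes of 35EbiT x Blimp1-GFP reporter mice of 6 to 8 weeks of age. Per the labels' protocols, CD4 T cells were enriched with magnetic beads before the sort, the typical purity was above 90%, and libraries were made with the SMART-Seq v4 Ultra Low Input RNA Kit from 10 pg to 10 ng of total RNA. Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12, HTSeq 0.6.1 and the genome build mm9 were used. Which tool did which step, the annotation and the counting mode are not given in the sources used here. The authors deposited FPKM values per gene in 2 tables, with replicates 1 and 2 of both populations in the first and replicates 3 and 4 in the second, and no other columns. Each library was taken from the column that carried the name in its title.

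The tables held 47709 and 47681 features. Unannotated features without an Ensembl identifier (640 and 612) were left out, which left 47069 Ensembl genes present in both tables. Symbols were taken for 46488 of them from a reference table of gene names (GENCODE, GRCm38), and 581 had none. Because the notes name mm9, no coordinates are given, and the reference served only for names, exon lengths, exon overlaps and the order of neighbouring genes. The low values of each library were whole multiples of what 1 read is worth, which gave the depth behind the deposited FPKM values of each library, from 13.3 M fragments (M, mega) in Ebi3-Treg 3 to 31.3 M in Blimp1-Treg 1. Reads in genes made up 92.3% to 94.0% of that depth. Reads per gene came out whole, within a tolerance of 0.01, for 99.9% of the genes, with the reference exon length for 26142 genes and with the shortest length that fitted for 20728. The latter lengths were chosen to make the reads whole, so for those genes wholeness is no check. With the reference length, 34.9% to 45.5% of the values above 0 in a library were whole. A low-input kit amplifies its cDNA, and reads without molecular identifiers are not independent molecules, so these limits cover counting error only. Such a kit does not mark the strand as far as the labels say, and the counting mode is not known, so values of near-identical paralogs (granzymes, Ccr1 and Ccr3, ribosomal proteins with pseudogenes, histones) and of overlapping genes are uncertain where reads could be shared.

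Genes with at least 1 FPKM in at least 4 of the 8 libraries were tested, which kept 12273 genes, 41 of them without a symbol. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with population and table as terms, moderated variances with a trend and Benjamini-Hochberg adjusted p under 0.05, two-sided. All adjusted p for genes come from this fit unless another is named. The table term makes the contrast an average of differences within tables, because each library was scaled on its own and the tables may have been made separately. Levels set side by side across tables carry that limit. Log2 fold changes are Ebi3-Treg minus Blimp1-Treg on the log2(FPKM + 1) scale, which understates the change of low genes. Each table was also fitted alone, and the difference of the contrast between tables was fitted as an interaction. Gene lists (34, of which 31 had at least 5 tested genes) were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated, and with fry. Camera adjusted p are over the 31 lists. Nothing in the labels says that replicates came from separate animals, so p values measure the spread between these samples, which may be technical.

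The design, the gene lists, the other settings to try and the rule for the genes named were chosen before the data were examined. The rule took all sort and reporter genes, the 10 largest changes in each direction among genes past the threshold with a mean of at least 5 FPKM in the higher population and the same direction in both tables (leaving out antigen receptor segments, pseudogenes, microRNAs and unnamed models), and of each list the 4 members with the smallest unadjusted p. It named 141 genes, Il12a among them though too low to be tested, of which 74 were past the threshold. Other genes named were chosen after their values were seen, namely Cd79a, Xist and those of the closing section. Results on some genes are not reported here.

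Libraries with the same number deviated together from their population means, across genes, with r = 0.62, 0.89, 0.53 and 0.54 for numbers 1 to 4. Against the Blimp1-Treg library of the other number in the same table, r was -0.27, -0.02, 0.56 and 0.61 for Ebi3-Treg 1 to 4. The data, not the labels, thus pair the samples for numbers 1 and 2, while the r of 3 and 4 goes with their table. The replicate block was planned and uses all 4 numbers. Relative to the mean of each population in its own table the correlation was 0.85 for numbers 1 and 2 and -0.08 for 3 and 4, so within the second table the numbers 3 and 4 did not pair. Values from a fit with the replicate number as a block are given for part of the genes and lists. Where none is given, a call or count may still have changed. The first principal component (51.8% of the variance) set both libraries numbered 2 apart, and the second (22.3%) separated the populations. Between libraries of a population the correlation was 0.90 to 0.97 for Ebi3-Treg and 0.87 to 0.98 for Blimp1-Treg, so none was an identical copy of another. This does not settle whether libraries shared animals or RNA.

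The scripts were tested on simulated data in which 200 of 12249 genes were changed between the populations. The fit with the table term recovered 0 of 50 genes changed 1.5-fold, 8 of 50 changed 2-fold (16%), 43 of 50 changed 4-fold (86%) and 48 of 50 changed 8-fold (96%), with 0 false calls. The fit with the block recovered 32, 48, 50 and 50 with 16 false calls. Simulated libraries of the same number shared their means, and 1 spread from the block fit served all genes. Pairing of all 4 numbers was thus built in, which the real numbers 3 and 4 did not show. The better recovery with the block therefore does not say which fit suits the real data. Alternatives were the pseudocount (0.1 and 0.01), the filter (none, or 5 FPKM), median-ratio and quantile scaling, no table term, the replicate block, no variance trend, array weights and each library left out in turn. Added after seeing the data were limma-voom on the recovered reads, a block for numbers 1 and 2 only, both libraries numbered 1 or both numbered 2 left out, and the block together with an estimated correlation. A planned count-model test was not run because the deposited unit is FPKM. Tables were joined and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.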

Results

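Regulatory T cells (Tregs) restrain immune responses and depend on the transcription factor Foxp3. Transcripts were measured by RNA sequencing in 2 Treg populations sorted from the lymph nodes of C57BL/6 mice that carried both the 35EbiT reporter and a GFP knock-in at Blimp1 (gene symbol Prdm1). Ebi3-Treg cells were Thy1.1-positive and Blimp1-negative, and Blimp1-Treg cells were Thy1.1-negative and Blimp1-positive. Both were CD4-positive and CD25-positive. Ebi3 encodes a subunit of the cytokines IL-35 and IL-27, and Blimp1 is a transcriptional repressor of effector lymphocytes. Each population had 4 libraries, numbered 1 to 4. Replicates 1 and 2 of both populations were deposited in one table of FPKM values (fragments per kilobase and megafragment) and replicates 3 and 4 in another. The depth behind the FPKM values was 25.6, 20.2, 13.3 and 22.1 M fragments (M, mega) for Ebi3-Treg 1 to 4, and 31.3, 19.5, 19.2 and 14.7 M for Blimp1-Treg 1 to 4. At these depths a single read in a gene of 1 kb was worth 0.0320 to 0.0750 FPKM. Between 25132 and 35548 genes had a value above 0 in a library, and 12273 genes entered the tests.

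The comparison asks which transcripts distinguish Tregs marked by the Ebi3 reporter from Tregs marked by Blimp1. Ebi3 and Prdm1, the genes behind the reporters, separated the populations in every library, and so did Il10, which was not gated on. Ebi3 (ENSMUSG00000003206) was at 29.6 ± 11.7 FPKM in Ebi3-Treg and 7.67 ± 2.84 FPKM in Blimp1-Treg (SD, n = 4), a log2 fold change of 1.80 (SE 0.25, adjusted p = 0.00576), with 1.82 in replicates 1 and 2 and 1.79 in replicates 3 and 4. Prdm1 (ENSMUSG00000038151) was at a mean of 3.31 FPKM in Ebi3-Treg and 94.2 FPKM in Blimp1-Treg (n = 4), a log2 fold change of -4.43 (SE 0.23, adjusted p = 0.000155), with -4.34 in replicates 1 and 2 and -4.53 in replicates 3 and 4. Il10, which encodes an inhibitory cytokine, was lower in Ebi3-Treg by a log2 fold change of -5.35 (SE 0.50, adjusted p = 0.00124), with 5.19 ± 1.80 FPKM in Ebi3-Treg against 320 ± 241 FPKM in Blimp1-Treg (SD, n = 4), and with -6.47 in replicates 1 and 2 and -4.23 in replicates 3 and 4. Il12a, which encodes the other chain of IL-35, reached at most 1.49 FPKM in any library and was too low to be tested.

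Cd4 and Il2ra, which stand for the part of the gate shared by both populations, did not pass the test. Foxp3, on which the cells were not gated, did not pass either. Foxp3 was at 292 ± 90.0 FPKM in Ebi3-Treg and 313 ± 95.6 FPKM in Blimp1-Treg (SD, n = 4), with a log2 fold change of -0.10 (SE 0.19, adjusted p = 0.886). The log2 fold changes were -0.10 for Cd4 (adjusted p = 0.896) and -0.27 for Il2ra, which encodes CD25 (adjusted p = 0.669). Thy1 had a log2 fold change of 0.43 (adjusted p = 0.375, with 0.0136 with the replicate number as a block). The FPKM values do not separate the Thy1.1 allele from the Thy1 gene of the C57BL/6 mouse. Of the 8 sort and reporter genes tested, 1 was higher, 2 were lower and 5 did not pass, and adjusted over the list alone 2 were higher and 2 lower. The block gave 3 higher and 2 lower. The list as a whole had a median log2 fold change of -0.10 and a camera adjusted p of 0.329.

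**Figure D1:**
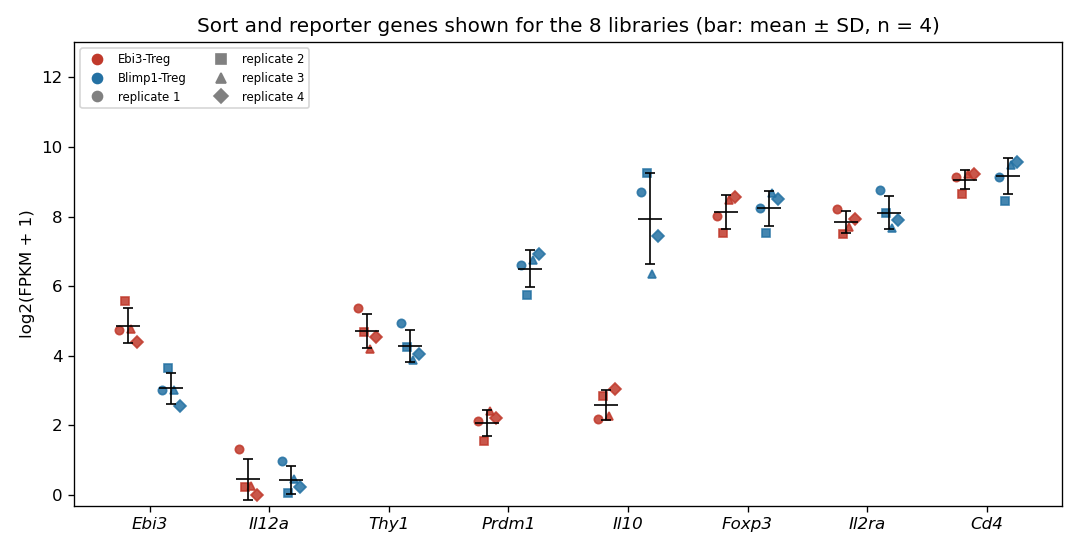
Expression of 8 of the sort and reporter genes as log2(FPKM + 1) on the vertical axis, with 1 point for each of the 8 libraries and a bar for the mean ± SD (n = 4) of each population. Ebi3 points of Ebi3-Treg lie above those of Blimp1-Treg, Prdm1 and Il10 points lie far below them, and Foxp3 and Cd4 points overlap.

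Of the 12273 genes tested with both tables together, 413 were higher and 359 lower in Ebi3-Treg, 772 in all, and 520 of these differed at least 2-fold. The largest increases were in Wnt10a, which encodes a secreted Wnt ligand (27.5 ± 6.96 against 0.193 ± 0.129 FPKM, SD, n = 4, log2 fold change 4.56, SE 0.21, adjusted p = 0.000104), Lad1 (4.01), Nsg2 (3.86), the calpain protease gene Capn3 (3.76), Plagl1 (3.50), the glutathione transferase gene Gsta4 (3.27), the actin regulator gene Evl (3.24), Ccr7 (3.12), the chemokine gene Cx3cl1 (3.04) and Serpinc1, which encodes antithrombin (2.99). The largest decreases were in Gzmb, which encodes the protease granzyme B (0.639 ± 1.08 against 108 ± 74.6 FPKM, SD, n = 4, log2 fold change -5.93, SE 0.38, adjusted p = 0.00031), Ccr2 (-5.38), Il10, Prdm1, Sccpdh (-4.15), Neb, which encodes a muscle filament protein (-3.86), the inhibitory receptor gene Havcr2 (-3.40), the cytokine gene Il17a (-3.37) and the inhibitory receptor gene Lag3 (-3.36). Adjusted p values of these genes ran from 0.000104 for Wnt10a to 0.0138 for Il17a.

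All 772 genes had the same direction in both tables, and in 771 the populations did not overlap within either table, which the selection on the average of both tables nearly fixes. Of all 12273 genes tested, 69.7% had the same direction in both tables. No overlap within either, with the same direction in both, held for 2337 (19.0%). Chance gives 5.56% if the libraries of a table are exchangeable. The shared deviations of libraries with the same number, 1 or 2, go against that. The count was 2752 (1655 higher and 1097 lower) with the replicate number as a block, and these 2752 included all 772. It was 1970 without both libraries numbered 1, which held B cell transcripts, and 1962 without both libraries numbered 2, which stood apart from the rest. It was 385 without Ebi3-Treg 3, 370 without Ebi3-Treg 4, 403 without Blimp1-Treg 3 and 341 without Blimp1-Treg 4.

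**Figure D2:**
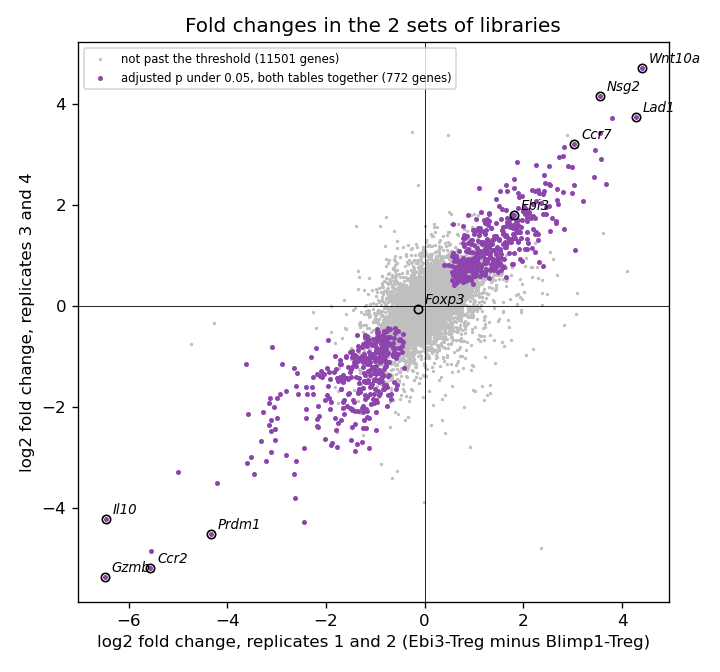
Log2 fold change of each of the 12273 tested genes, Ebi3-Treg minus Blimp1-Treg on the log2(FPKM + 1) scale, in replicates 1 and 2 (horizontal axis) and in replicates 3 and 4 (vertical axis). The 772 genes past the threshold lie in the 2 quadrants where both sets of libraries have the same direction, while Foxp3 lies near 0 in both.

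Within the tables, replicates 3 and 4 alone called 1347 genes (676 higher and 671 lower in Ebi3-Treg), and 1267 of them (94.1%) had the same direction in replicates 1 and 2. With limma that count was 0 without the filter on low values, where 40415 genes were tested, and 764 without the variance trend. Wnt10a differed by a log2 fold change of 4.40 in replicates 1 and 2 and 4.71 in replicates 3 and 4, and Ccr2 by -5.56 and -5.20. Replicates 1 and 2 alone called 0 of 12273 genes with limma, with 707 at an unadjusted p under 0.05, a share near the 0.05 that chance gives. They called 2855 with the replicate number as a block. That blocked fit left 1 residual degree of freedom, so its calls lean on the variance moderated across genes. Of 971 genes called in replicates 3 and 4 and in blocked replicates 1 and 2, 962 (99.1%) had the same direction. Across genes, which are not independent replicates, the log2 fold changes of the tables correlated with a Pearson r of 0.68 and a Spearman rho of 0.57. A test of the difference itself called 0 genes with limma, with 203 at an unadjusted p under 0.05, and 13 with the block. The 203 are fewer than chance gives at that threshold, so the 0 calls do not show that the tables have the same differences. The count for replicates 1 and 2 was 10 without Ebi3-Treg 1, 8 without Ebi3-Treg 2, 76 without Blimp1-Treg 1 and 59 without Blimp1-Treg 2. The count for replicates 3 and 4 was 455 without Ebi3-Treg 3, 485 without Ebi3-Treg 4, 143 without Blimp1-Treg 3 and 154 without Blimp1-Treg 4. The table also coincided with the sex of the mice, since Xist was at 0.0750 FPKM or less in replicates 1 and 2 and at 18.5 to 24.4 FPKM in replicates 3 and 4, so sex and table cannot be told apart.

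Genes of effector Tregs were lower in Ebi3-Treg. Of 23 tested, 13 were lower, 0 higher and 10 did not pass, with 14 lower when adjusted over the list alone. Next to Gzmb, Il10, Havcr2 and Lag3, the lower genes included Tigit, which encodes a co-inhibitory receptor (45.8 ± 10.3 against 232 ± 42.3 FPKM, SD, n = 4, log2 fold change -2.32, SE 0.18, adjusted p = 0.000546), and Fgl2, which encodes a secreted suppressive protein (-2.69, SE 0.24). Maf (-1.83), Icos (-1.57), Klrg1 (-2.02) and Il1rl1 (-1.24), which encodes the IL-33 receptor, were lower as well. The median log2 fold change was -1.04 and the camera adjusted p was 2.02e-16. It was 0.00695 with an estimated correlation, under which this was the 1 list still called, and 0.157 with an estimated correlation and the replicate block. Klrg1 was not called without Ebi3-Treg 2, 3 or 4 or Blimp1-Treg 1, 2 or 3 (adjusted p up to 0.106), nor Il1rl1 without any library but Blimp1-Treg 4 (up to 0.149).

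Inhibitory receptors went both ways. Of 14 tested, 3 were higher, 5 lower and 6 did not pass, and adjusted over the list alone 5 were higher and 5 lower. The block gave 5 higher and 6 lower. Havcr2, Lag3 and Tigit were lower, whereas Cd96 had a log2 fold change of 1.95 (224 ± 39.5 against 58.3 ± 16.8 FPKM, SD, n = 4, SE 0.20, adjusted p = 0.00206) and Cd160 one of 2.16 (SE 0.27, adjusted p = 0.00386). The list was not called (median -0.48, camera adjusted p = 0.155), though it was with the 5 FPKM filter (median -0.72, adjusted p = 0.0338) and with fry (0.00188). Cytotoxic and chemokine ligand genes had 1 higher, 3 lower and 11 not passing of 15 tested, with 1 higher and 8 lower when adjusted over the list alone and 1 and 7 with the block. Gzmk (-2.86, SE 0.42, adjusted p = 0.00726) and Gzmc (-1.51, SE 0.24, adjusted p = 0.00989, with 0.0571 at a pseudocount of 0.01 and 0.169 without the table term) were lower beside Gzmb, and Lamp1, which encodes a lysosomal membrane protein, was higher (1.13, SE 0.12). The camera adjusted p of this list was 0.000104 (median -0.91), with an adjusted p = 0.183 with an estimated correlation.

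Genes of central or resting T cells were higher in Ebi3-Treg. Of 17 tested, 7 were higher, 0 lower and 10 did not pass, and 14 were higher when adjusted over the list alone, as with the replicate block. Ccr7, the receptor that guides T cells into lymph nodes, was at 712 ± 701 against 74.3 ± 54.3 FPKM (SD, n = 4, log2 fold change 3.12, SE 0.34, adjusted p = 0.00252). Tcf7, which encodes the transcription factor TCF-1, was at 583 ± 117 against 96.3 ± 41.7 FPKM (SD, n = 4, log2 fold change 2.70, SE 0.31, adjusted p = 0.0028). Id3 (2.65, SE 0.17) and Treml2 (2.16, SE 0.30) were higher too. The list had a median of 1.09 and a camera adjusted p of 1.87e-08, with an adjusted p = 0.291 with an estimated correlation.

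Genes typical of conventional CD4 T cells, a population the sort could hold, had 5 higher, 1 lower and 4 not passing of 10 tested, with 8 higher and 1 lower when adjusted over the list alone, as with the replicate block. Cd40lg, which encodes the ligand of CD40, was higher by a log2 fold change of 1.69 (79.9 ± 14.5 against 23.9 ± 2.99 FPKM, SD, n = 4, SE 0.17, adjusted p = 0.00178), and Cd226 by 1.01 (SE 0.15, adjusted p = 0.00705). Il21, which encodes a cytokine that helps B cells, was lower (-1.02, SE 0.15, adjusted p = 0.00838). The list shares genes such as Tcf7 with that of central or resting T cells. Its median was 1.05 and its camera adjusted p was 0.000603, with an adjusted p = 0.27 with an estimated correlation. Foxp3 was at 292 ± 90.0 FPKM in the same Ebi3-Treg libraries (SD, n = 4). A level over all cells of a library cannot tell whether some cells lacked Foxp3, and this was not tested.

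Treg identity genes were not called as a list. Of 15 tested, 2 were higher, 2 lower and 11 did not pass, adjusted over the list alone 4 were higher and 2 lower, and with the replicate block 4 and 4. The signalling inhibitor gene Socs2 was lower (46.0 ± 17.8 against 131 ± 68.4 FPKM, SD, n = 4, log2 fold change -1.40, SE 0.20, adjusted p = 0.007), and so was Capg (-0.98). Nrp1 (102 ± 15.1 against 52.5 ± 28.6 FPKM, SD, n = 4, adjusted p = 0.0296) and Gpr83 (log2 fold change 1.08) were higher. The list median was -0.10 and the camera adjusted p 0.578. When single libraries were left out, Capg was not called without replicate 3 or 4 of either population or Blimp1-Treg 1 or 2 (adjusted p up to 0.109), Nrp1 without any library but Blimp1-Treg 3 (up to 0.0839) and Gpr83 without any library but Ebi3-Treg 2 (up to 0.154).

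Of 23 chemokine and homing receptors tested, 2 were higher, 8 lower and 13 did not pass, with 3 higher and 10 lower when adjusted over the list alone. The block gave 4 higher and 12 lower. Ccr2, a receptor of inflammatory chemokines, was at 2.01 ± 1.71 against 118 ± 44.4 FPKM (SD, n = 4), and Ccr1 was lower by a log2 fold change of -2.21 (SE 0.25, adjusted p = 0.00296). Ccr7 was higher. The list had a median of -0.59 and a camera adjusted p of 1.33e-05, with an adjusted p = 0.209 with an estimated correlation.

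Cytokine genes had 5 higher, 3 lower and 12 not passing of 20 tested, with 7 higher and 4 lower when adjusted over the list alone. The block gave 8 higher and 4 lower. Lta, which encodes lymphotoxin alpha, was higher (116 ± 33.8 against 23.4 ± 7.71 FPKM, SD, n = 4, log2 fold change 2.27, SE 0.16, adjusted p = 0.000455), as was Tnfsf11, which encodes RANK ligand (1.82, SE 0.24, adjusted p = 0.00503). Il10 was lower, and Il17a was at 0.464 to 5.61 FPKM in Ebi3-Treg libraries against 10.5 to 52.1 FPKM in Blimp1-Treg libraries. Il17a was not called without Ebi3-Treg 3 or 4 or Blimp1-Treg 3 or 4 (adjusted p up to 0.0586). The list was not called (median 0.36, camera adjusted p = 0.261). Of 25 cytokine receptor genes 2 were higher, 1 lower and 22 did not pass, with 2 higher and 2 lower when adjusted over the list alone and 6 and 6 with the block. Ifngr2, which encodes a chain of the interferon gamma receptor, was higher (1.75, SE 0.24, adjusted p = 0.00542), as was Ifnar2 (0.72, SE 0.12, adjusted p = 0.013), whose call was lost without Ebi3-Treg 3 or 4 or Blimp1-Treg 3 or 4 (adjusted p up to 0.0694). Il12rb1 had a log2 fold change of -1.32 (adjusted p = 0.0579), with 0.000659 under the replicate block. The receptor list had a median of -0.17 and a camera adjusted p of 0.426.

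Transcription factors of T helper lineages split between the populations. Of 26 tested, 5 were higher, 6 lower and 15 did not pass, adjusted over the list alone 8 were higher and 6 lower, and with the replicate block 10 and 10. Id3 and Tcf7 were higher, and Maf (17.2 ± 1.97 against 65.5 ± 18.4 FPKM, SD, n = 4, log2 fold change -1.83, SE 0.20, adjusted p = 0.00252) and Hif1a, which encodes a factor of the response to low oxygen (-0.93, SE 0.12, adjusted p = 0.00477), were lower. The list median was -0.20 and its camera adjusted p 0.398. Follicular T cell genes had 3 higher, 2 lower and 8 not passing of 13 tested, with 4 higher and 2 lower when adjusted over the list alone and 6 and 2 with the block. Bcl6, which encodes the repressor that directs follicular T cells, was higher (10.3 ± 1.25 against 3.40 ± 1.64 FPKM, SD, n = 4, log2 fold change 1.43, SE 0.22, adjusted p = 0.00838), as was Slamf6 (0.80), whereas Icos and Il21 were lower. Slamf6 was not called without Ebi3-Treg 2, 3 or 4 or Blimp1-Treg 3 or 4 (adjusted p up to 0.0869). The follicular list was not called (median 0.19, camera adjusted p = 0.76).

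**Figure D3:**
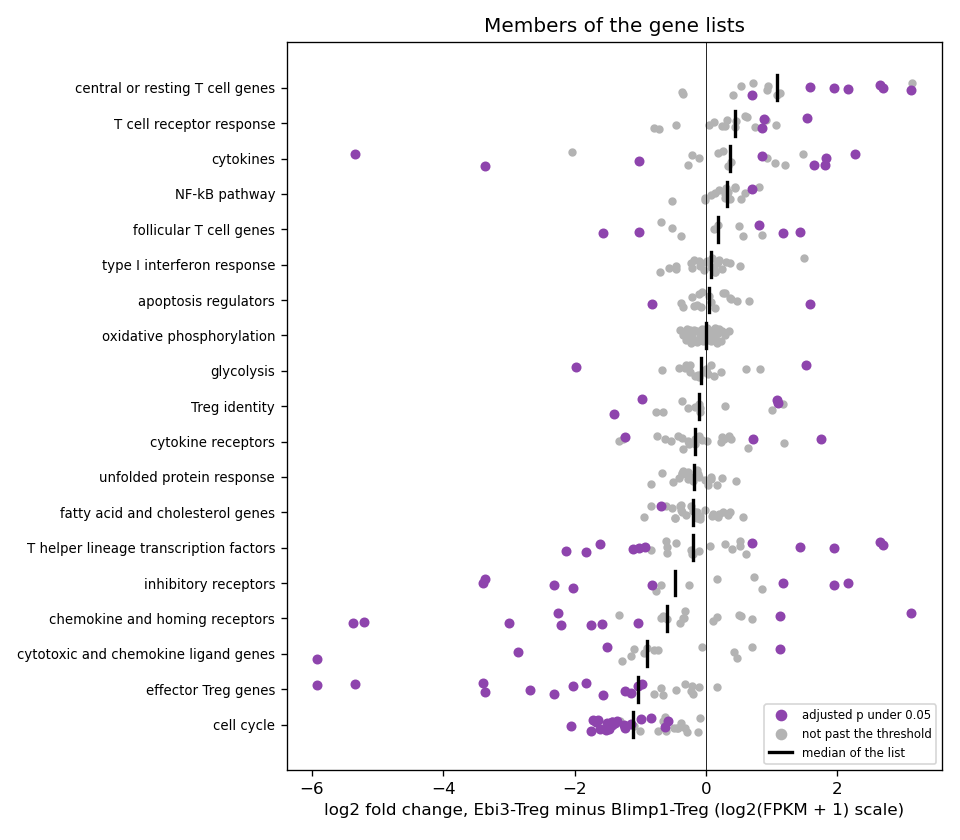
Log2 fold change (Ebi3-Treg minus Blimp1-Treg, log2(FPKM + 1) scale, horizontal axis) of each tested member of 19 gene lists, with members past the threshold in purple and the list median as a black bar. Central or resting T cell genes have a median of 1.09, and the medians of effector Treg and cell cycle genes are -1.04 and -1.12.

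Cell cycle genes were lower in Ebi3-Treg. Of 38 tested, 22 were lower, 0 higher and 16 did not pass, with 32 lower when adjusted over the list alone, and all 38 had a negative log2 fold change. Rrm2, which encodes a subunit of ribonucleotide reductase, was at 33.0 ± 16.5 against 107 ± 30.1 FPKM (SD, n = 4, log2 fold change -1.76, SE 0.16, adjusted p = 0.00124). The mitotic genes Birc5 (-1.65, SE 0.17), Ccnb2 (-1.52, SE 0.19) and Nusap1 (-1.72, SE 0.23) were lower. The list median was -1.12 and its camera adjusted p 3.02e-28, with an adjusted p = 0.209 with an estimated correlation. Of 10 canonical histone genes tested 0 were higher, 2 lower and 8 did not pass, with 1 higher and 2 lower when adjusted over the list alone. The lower genes were Hist1h1b (-1.12, SE 0.18, adjusted p = 0.00966) and Hist1h2ap (-1.39, SE 0.23, adjusted p = 0.0114), of which Hist1h2ap was not called without Blimp1-Treg 4 (adjusted p = 0.0562). The histone list had a median of 0.10, a mean of -0.13 and a camera adjusted p of 0.253 in the direction of the mean. The block gave 1 higher and 3 lower histone genes. Among 19 apoptosis regulators, Bcl2, which protects cells from death, was higher (24.9 ± 7.72 against 7.58 ± 1.87 FPKM, SD, n = 4, log2 fold change 1.58, SE 0.26, adjusted p = 0.0114), 1 gene was lower and 17 did not pass, with the same 1 higher and 1 lower when adjusted over the list alone. Apoptosis regulators had a camera adjusted p of 0.973, with a median of 0.04 and a mean of 0.10 against a test direction of lower. Of these regulators the block called 3 as higher and 2 as lower.

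Of 20 glycolysis genes 1 was higher, 1 lower and 18 did not pass, with 2 higher and 1 lower when adjusted over the list alone. The block gave 2 higher and 4 lower. The lactate transporter gene Slc16a3 was lower (10.6 ± 2.61 against 47.1 ± 19.1 FPKM, SD, n = 4, log2 fold change -1.99, SE 0.30, adjusted p = 0.00811) and the enolase gene Eno3 was higher (1.52, SE 0.24, adjusted p = 0.0109). The glycolysis list had a median of -0.08 and a camera adjusted p of 0.329. None of 50 oxidative phosphorylation genes passed (0 higher and 0 lower, also when adjusted over the list alone, 1 higher with the block, with a median of 0.00 and a camera adjusted p of 0.578). That list was called as higher without Ebi3-Treg 1 (median 0.25, adjusted p = 0.00941) or Blimp1-Treg 2 (0.25, adjusted p = 0.0178) and as lower without Ebi3-Treg 2 (-0.15, adjusted p = 0.0257) or Blimp1-Treg 1 (-0.14, adjusted p = 0.0357). Of 27 fatty acid and cholesterol genes, 1 was lower, 0 higher and 26 did not pass, adjusted over the list alone 0 passed, and with the replicate block 3 were higher and 12 lower. It was Fdft1, which encodes squalene synthase (-0.68, SE 0.15, adjusted p = 0.0395), and its call was lost without any 1 of the 8 libraries (adjusted p up to 0.149). Fabp5 had a log2 fold change of -0.95 (adjusted p = 0.0595, with 0.0111 under the replicate block). The list had a median of -0.19 and a camera adjusted p of 0.00874, with an adjusted p = 0.429 with an estimated correlation.

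Few genes induced by T cell receptor signals passed the test, though the list was called as higher in Ebi3-Treg. Of 18 tested, 3 were higher, 0 lower and 15 did not pass, with 7 higher and 2 lower when adjusted over the list alone and 8 and 3 with the block. Myc, which encodes a driver of cell growth, was higher (148 ± 29.4 against 50.6 ± 10.9 FPKM, SD, n = 4, log2 fold change 1.54, SE 0.21, adjusted p = 0.006), as were Nr4a1 (0.85, adjusted p = 0.021) and Dusp2 (0.88, adjusted p = 0.0499). Nr4a1 was not called without Ebi3-Treg 3 or 4 or Blimp1-Treg 3 or 4 (adjusted p up to 0.0927), nor Dusp2 without any library but Blimp1-Treg 1 (up to 0.174). The list had a median of 0.45 and a camera adjusted p of 0.0257, with an adjusted p = 0.27 with an estimated correlation and 0.101 without Ebi3-Treg 2. Among 19 genes of the NF-kB pathway 1 was higher, 0 lower and 18 did not pass, with 1 higher and 0 lower when adjusted over the list alone and 8 and 1 with the block. It was Tnfaip3, which encodes the NF-kB inhibitor A20 (0.69, SE 0.15, adjusted p = 0.036), and it was not called without replicate 3 or 4 of either population or Blimp1-Treg 1 or 2 (adjusted p up to 0.131). The NF-kB list had a median of 0.32 and a camera adjusted p of 0.0203, with an adjusted p = 0.492 with an estimated correlation, 0.0594 without Ebi3-Treg 2 and 0.061 without Blimp1-Treg 2.

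Immediate early genes, which cell handling can induce, were called as higher in Ebi3-Treg as a list, though few passed singly. Of 19 tested, 4 were higher, 0 lower and 15 did not pass, with 9 higher and 1 lower when adjusted over the list alone and 9 and 0 with the block. They were Btg2 (0.83, adjusted p = 0.00908), Ppp1r15a (0.71, adjusted p = 0.0195), Junb (0.73, adjusted p = 0.0249) and Fos (0.61, adjusted p = 0.036). Btg2 was not called without Ebi3-Treg 4 or Blimp1-Treg 4 (adjusted p up to 0.0535), nor Ppp1r15a without replicate 3 or 4 of either population (up to 0.0979). Junb was not called without these or Blimp1-Treg 1 or 2 (up to 0.122), nor Fos without any library but Ebi3-Treg 1 (up to 0.153). The list had a median of 0.50 and a camera adjusted p of 0.00874, with an adjusted p = 0.357 with an estimated correlation and 0.0594 without Ebi3-Treg 2. None of 13 heat shock genes passed, also when adjusted over the list alone (1 higher with the block), with a median of 0.08 and a camera adjusted p of 0.868.

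No gene of the unfolded protein response or the type I interferon response passed the test. The 22 unfolded protein response genes had a median of -0.18 and a camera adjusted p of 0.0271, with an adjusted p = 0.466 with an estimated correlation. The chaperone gene Hsp90b1 had a log2 fold change of -0.67 (adjusted p = 0.107, with 0.00325 under the replicate block), and Pdia4 one of -0.51 (adjusted p = 0.0824, with 0.00349 under the block). The call of this list was lost without Ebi3-Treg 1 (adjusted p = 0.189), Ebi3-Treg 3 (0.0932), Blimp1-Treg 2 (0.189) or Blimp1-Treg 4 (0.0547). The 26 interferon response genes had a median of 0.08 and a camera adjusted p of 0.587 in the direction of lower, with a log2 fold change of 1.49 for Usp18 (adjusted p = 0.0658, with 0.00191 under the block). Adjusted over the list alone, 0 genes of either list passed, and with the block 1 was higher and 5 lower of the unfolded protein response and 3 and 1 of the interferon response.

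Ribosomal protein genes were higher in Ebi3-Treg as a list. Of 77 tested, 3 were higher, 0 lower and 74 did not pass, also when adjusted over the list alone, and 33 were higher with the replicate block. They were Rpl8 (337 ± 145 against 205 ± 85.7 FPKM, SD, n = 4, log2 fold change 0.72, adjusted p = 0.0181), Rpl3 (0.65, adjusted p = 0.0186) and Rps2 (0.60, adjusted p = 0.0262), and each lost its call without Ebi3-Treg 3 or 4 or Blimp1-Treg 3 or 4, Rpl3 and Rps2 also without Blimp1-Treg 1 and Rps2 without Ebi3-Treg 2 (adjusted p up to 0.0886, 0.0954 and 0.111). The median was 0.51 and the camera adjusted p 1.08e-07, with an adjusted p = 0.68 with an estimated correlation. The mean log2(FPKM + 1) of the list was 8.01 in Ebi3-Treg 2 and 7.91 in Blimp1-Treg 2 against 5.29 to 7.13 in the other libraries. The 12 mitochondrially encoded genes tested followed the same libraries, with means of 6.69 and 6.76 in the libraries numbered 2. None of the 12 passed, also when adjusted over the list alone, and 6 were higher with the replicate block. Their median was 0.58 and the camera adjusted p 0.02, with an adjusted p = 0.68 with an estimated correlation, and the call was lost without Ebi3-Treg 2 (0.169), Ebi3-Treg 3 (0.0932), Blimp1-Treg 1 (0.24), Blimp1-Treg 3 (0.0533) or Blimp1-Treg 4 (0.0547).

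Markers of other lymph node cells differed between single libraries. B cell transcripts were high in the libraries numbered 1, with Cd79a, which encodes a chain of the B cell receptor complex, at 65.1 FPKM in Ebi3-Treg 1 and 52.0 FPKM in Blimp1-Treg 1 against at most 2.31 FPKM in the other libraries. None of 12 B cell markers tested passed, also when adjusted over the list alone (median 0.27, camera adjusted p = 0.649). With the replicate block 5 were higher and 1 lower, among them Cd22 (log2 fold change 1.22, adjusted p = 0.29, with 0.000928 under the block), Cd72 (1.03, 0.138 and 0.00109), Bank1 (1.37, 0.413 and 0.00843) and Ighm (-0.43, 0.209 and 0.0482). Ighm lay between 1154 and 2214 FPKM in all 8 libraries. Of 9 plasma cell markers 1 was higher, 0 lower and 8 did not pass, also when adjusted over the list alone. It was Derl3, which encodes a protein of the endoplasmic reticulum (1.72, SE 0.18, adjusted p = 0.00207). Igkc, the kappa light chain gene, had a log2 fold change of -2.01 (adjusted p = 0.399). The plasma cell list had a median of -0.95 and a camera adjusted p of 0.433, and it was called as lower without Ebi3-Treg 1 (median -1.77, adjusted p = 0.0241).

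Myeloid transcripts were high in Ebi3-Treg 1 and 2. Lyz2, which encodes lysozyme, was at 99.1 and 91.1 FPKM there against 8.00 and 20.4 FPKM in Ebi3-Treg 3 and 4 and 3.74 to 29.9 FPKM in Blimp1-Treg. Of 9 macrophage, monocyte and neutrophil markers tested 0 passed over all genes, and adjusted over the list alone 6 were higher in Ebi3-Treg. Their median was 1.13 and the camera adjusted p 0.00874, with an adjusted p = 0.493 with an estimated correlation, 0.11 without both libraries numbered 1 and 0.0825 without both libraries numbered 2. C1qc (adjusted p = 0.0505), Apoe (0.0686), Fcer1g (0.0859) and Lyz2 (0.092) were higher with the replicate block (adjusted p = 0.0182, 0.0135, 0.0437 and 0.016). None of 11 dendritic cell and MHC class II genes passed, also when adjusted over the list alone (median 0.42, camera adjusted p = 0.345). With the block 2 were higher and 1 lower, Irf8 (0.75, adjusted p = 0.092, with 0.00614 under the block) and Cst3 (-0.55, 0.181 and 0.0218) among them. H2-Aa, which encodes an MHC class II chain, was at 167, 115, 9.18 and 5.87 FPKM in Ebi3-Treg 1 to 4 against 73.8 FPKM in Blimp1-Treg 1 and 2.93 to 6.09 FPKM in Blimp1-Treg 2 to 4.

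The remaining marker lists gave few calls. Of 10 genes of type 2 innate lymphoid cells, Klrg1 and Il1rl1 were lower, 0 were higher and 8 did not pass, with 3 higher and 2 lower when adjusted over the list alone (median -0.19, camera adjusted p = 0.836). The block gave 3 higher and 2 lower here as well. Fewer than 5 genes were tested for CD8 T and NK cells (4), erythroid cells and platelets (3) and lymph node stroma (3), so these lists had no set test. Among them 1 gene passed, Vim, which encodes the filament protein vimentin (226 ± 40.1 against 403 ± 85.3 FPKM, SD, n = 4, log2 fold change -0.82, SE 0.14, adjusted p = 0.0155), and its call was lost without Ebi3-Treg 3 or 4 or Blimp1-Treg 3 (adjusted p up to 0.0708). Adjusted over the list alone, Vim was lower and Pecam1 (0.77, adjusted p = 0.163 over all genes and 0.00285 with the block) higher in the stromal list, and 0 genes passed in the other 2 lists.

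**Figure D4:**
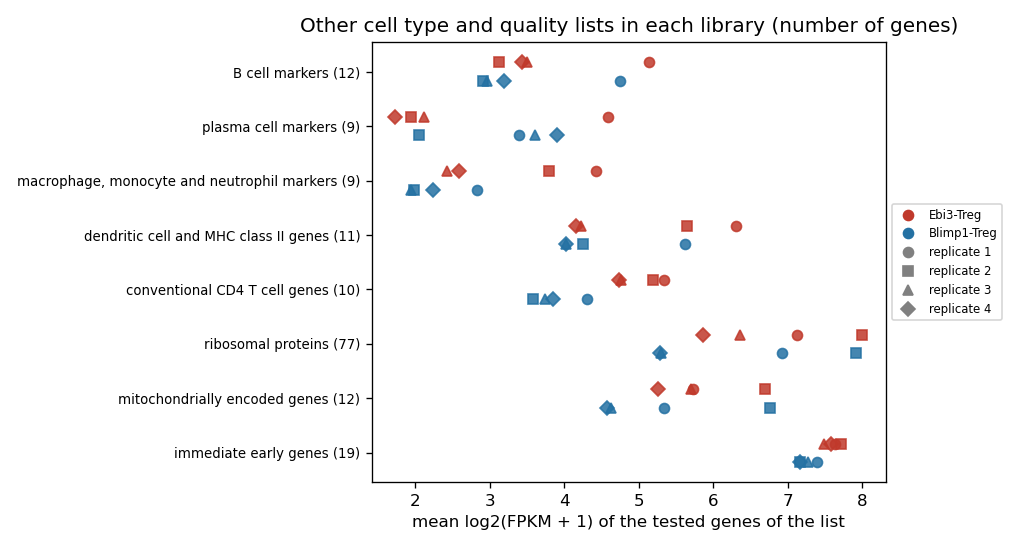
Mean log2(FPKM + 1) of the tested genes of 8 marker and quality lists (horizontal axis), with 1 point for each of the 8 libraries. B cell markers are highest in the libraries numbered 1, myeloid markers in Ebi3-Treg 1 and 2, and ribosomal protein and mitochondrially encoded genes in the libraries numbered 2.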

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

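Tests of the myeloid transcripts were chosen only after those values were seen, and the others beforehand. Restricting the splits of the libraries to those that part the pairs was not in the rule set beforehand. In 22 of 286 sets of 4 libraries, over 143 genes, the highest or lowest library stood apart from the other 3, with a gap large against the whole range, and chance gives about 1 in 20 such sets. Values are the gap as a share of the range, for the 21 sets given here.

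In Ebi3-Treg 1 the library stood above the others for Igha (0.992, 43.0 FPKM), Igkc (0.977, 402 FPKM), Gzmb (0.930, 2.26 FPKM against at most 0.159), Klrb1c (0.913), Gzma (0.886), Il12a (0.863, 1.49 FPKM against at most 0.205) and Bcl2 (0.855). In Ebi3-Treg 2 it did so for Tnfsf11 (0.946), Slamf6 (0.927), Hsp90b1 (0.877), Eno3 (0.869) and Capg (0.864). In Blimp1-Treg 1 it did so for H2-Ab1 (0.988, 121 FPKM against at most 9.81), H2-Aa (0.955, 73.8 FPKM against at most 6.09), Treml2 (0.939), Bank1 (0.936), Fcer1g (0.932) and Irf8 (0.848). Hspd1 was highest in Blimp1-Treg 2 (0.845), Nusap1 lowest in Blimp1-Treg 3 (0.883) and Klrb1c highest in Blimp1-Treg 4 (0.861).

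The difference between the populations was set among the 34 splits of the 8 libraries into 4 and 4, itself included, that the model could fit. The real split was the 1 that called as many as 772 genes, and the highest of the others called 4. Since the numbers were taken to pair the samples, the splits to compare are the 8 that part all 4 pairs, and these are too few for a share under 0.05. Among these 8 splits the highest other called 0 genes. For gene lists 2 of the 34 splits called 14 or more, the real split with 14 and another with 16, which set Ebi3-Treg 1 and Blimp1-Treg 1, 2 and 4 against the rest. That share is over the 0.05 set beforehand, so by that rule chance stays open for the number of lists. Among the splits that part all 4 pairs the highest other called 12 lists.

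Myeloid and MHC class II transcripts were high in Ebi3-Treg 1 and 2. B cells carried over in the sort may add to those of Ebi3-Treg 1, but in Ebi3-Treg 2 the ratio of excess H2-Aa to Cd79a was 46.7, which is 36.6 times the 1.28 of Blimp1-Treg 1, a library with B cell transcripts, and this argues against B cells there. Macrophages or dendritic cells stay open, since 24 of 33 of their markers that reached 1 FPKM (72.7%) were over 2-fold higher in the mean of Ebi3-Treg 1 and 2 than in the mean of 3 and 4, between the bounds set for and against them. That comparison is across the tables, which coincide with sex. Within the first table, 22 of the 33 were over 2-fold higher in that mean than in the mean of Blimp1-Treg 1 and 2. Ebi3-Treg 1, which held B cell transcripts, can raise such a mean alone. Fscn1 was at 30.8 FPKM in Ebi3-Treg 1 and 2.01 in Ebi3-Treg 2, and Mpeg1 at 3.42 and 0.514. Markers raised in each of the 2 libraries were not counted. Lyz2 at 91.1, Apoe at 40.6 and Fcer1g at 21.2 FPKM in Ebi3-Treg 2 go with such cells, and Csf1r at 0.486 and Ciita at 0.302 FPKM are low. Of these markers Irf8 and Bst2 also stand in other lists, and Cybb, Cd74 and Cst3 were at 46.8 FPKM or more in every library. Against the mean of Ebi3-Treg 3 and 4, 9 of the 33 were not raised over 2-fold in the mean of Ebi3-Treg 1 and 2. The CD4 enrichment and CD25 gate would remove such cells. With these limits, they cannot be told apart here from expression by Ebi3-Treg cells, which no test addressed.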

How the results depend on the processing

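Limma-voom on recovered reads, the block for numbers 1 and 2, the libraries numbered 1 or 2 left out together and the block with an estimated correlation were chosen after seeing the data. The count of 772 genes moved to 420 without a filter on low values, where 40415 genes were tested, 441 without the table term, 2752 with the replicate block, 2146 with array weights, 3016 with limma-voom and the replicate block, 2938 with the block for numbers 1 and 2, 1970 without both libraries numbered 1 and 1962 without both numbered 2. Leaving out 1 library gave 341 to 771. It lay between 567 and 996 with the other pseudocounts, the 5 FPKM filter, both scalings, no variance trend and limma-voom (755), and no called gene turned direction in any alternative. Median-ratio scaling moved the share of higher genes among the called from 53.5% to 44.9%, and the median of all genes from 0.07 to -0.01.

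The 14 lists called (8 higher, 6 lower) became 1 with an estimated correlation and 0 with the replicate block and an estimated correlation, and 11 to 15 with 1 library left out. Fry called 10, testing only whether a list moves 1 way. The median of oxidative phosphorylation turned to 0.22 with array weights and to 0.25 without Ebi3-Treg 1 and 0.25 without Blimp1-Treg 2, in a range of -0.15 to 0.25 with 1 library left out.

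In replicates 1 and 2 the count of 0 became 2855 with the replicate block and 8 to 76 with 1 library left out, which leaves a lone library assumed to vary like the other population. In replicates 3 and 4 the count of 1347 became 0 without a filter, 764 without the variance trend and 143 to 485 with 1 library left out. The difference between tables had 13 genes with the replicate block in place of 0, and 0 to 0 with 1 library left out. Of 74 named genes past the threshold, 47 were called in every alternative in which they were tested, since the 5 FPKM filter leaves out low genes, and 52 with each library left out, and 0 were lost with the replicate block. Those kept with each library left out but lost without the table term were Ccr7 (adjusted p = 0.0523), Socs2 (0.132), Birc5 (0.136), Hist1h1b (0.218) and Gzmc (0.169, and 0.0571 at a pseudocount of 0.01). Of 66 not past it, 42 were past it with the block. With camera at the preset correlation the block changed no list's call, while limma-voom with the block also called oxidative phosphorylation (adjusted p = 0.0192) and B cell markers (0.0255). The causes of these shifts were not tested, apart from the fewer libraries and other numbers of genes tested. Depth limits genes near 1 FPKM most in Ebi3-Treg 3, at 13.3 M fragments. The planned count-model test was not run because the deposited unit is FPKM.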

Other observations

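The genes in this part were chosen after their values were seen, and so were the genes beside Il12a. The check of these for overlapping exons was set before its result. Lgals3, which encodes a galectin, was lower in Ebi3-Treg, at 3.81 ± 4.12 against 35.4 ± 5.44 FPKM (SD, n = 4, log2 fold change -3.23, adjusted p = 0.00386), and Lgals1, which encodes another galectin, had a log2 fold change of -2.01. The leukotriene B4 receptor gene Ltb4r1 (-3.25), Metrnl (-3.01), the chemokine gene Ccl20 (-3.00), S100a6 (-2.69), the matrix protease gene Mmp9 (-2.41) and Anxa2 (-1.88) were lower, with adjusted p from 0.00044 for Metrnl to 0.0118 for Mmp9.

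Higher in Ebi3-Treg were Gata1, which encodes a transcription factor of red cell precursors (24.3 ± 3.14 against 3.46 ± 1.01 FPKM, SD, n = 4, log2 fold change 2.52, adjusted p = 0.00044), the cytokine gene Lif (8.18 ± 4.41 against 0.460 ± 0.263 FPKM, SD, n = 4, adjusted p = 0.011), Tgm2 (2.83), Nod1 (2.87), Maged2 (2.46) and Socs1, which encodes an inhibitor of cytokine signalling (1.40, adjusted p = 0.00893). Cd86, which encodes a costimulatory ligand, was at 83.4 ± 25.6 against 22.1 ± 9.22 FPKM (SD, n = 4, log2 fold change 1.90, adjusted p = 0.00594), Cd40 had a log2 fold change of 2.16 (adjusted p = 0.0302) and H2-Oa one of 2.30 (adjusted p = 0.00354). In replicates 3 and 4 the log2 fold changes were 2.27 for Cd86 and 2.08 for Cd40, and those of the myeloid and MHC class II genes Lyz2 and H2-Aa were 1.05 and 0.92.

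Genes beside Il12a were higher in Ebi3-Treg although Il12a itself was near the floor. The nearest tested genes on one side, 1110032F04Rik (log2 fold change 2.25, SE 0.15, adjusted p = 0.000389), Ift80 (2.29, SE 0.14, adjusted p = 0.00031) and Smc4 (1.06, SE 0.22, adjusted p = 0.0275), had a mean of 1.87. Among the other sort and reporter genes, the largest absolute mean of 3 neighbours was 1.41, beside Cd4. Because the genes were noticed first, whether chance gives such a run was not tested. In the reference 0 pairs of the 3 genes had overlapping exons, which argues against reads shared between them. Trim59 nearby had a log2 fold change of 0.49 (adjusted p = 0.0589).

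Y-linked genes matched the difference of Xist between the tables. Ddx3y was at 51.2 to 70.4 FPKM in replicates 1 and 2 and listed at 0 in replicates 3 and 4. Cd8b1 was at 7.66 to 32.1 FPKM in all 8 libraries, whereas Cd8a reached 7.21 FPKM at most. Actb was at 5708 and 6217 FPKM in Ebi3-Treg 1 and Blimp1-Treg 1 against 1253 to 2206 FPKM in the other libraries. The difference between replicates 2 and 1 went with gene length across genes, with a Spearman rho of -0.38 in Ebi3-Treg and -0.32 in Blimp1-Treg, while the log2 fold change between populations had a rho of -0.03 with length.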
